A study of Caenorhabditis elegans with 6 samples.

How the data were processed

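RNA from whole Caenorhabditis elegans of the N2 Bristol strain, labelled as L4 larvae, was measured on Affymetrix C. elegans arrays. Yolk and eggshell transcripts were abundant, so the stage at harvest is not settled by the sources used here. Per the labels' protocols, worms were broken open with glass beads in Trizol, the RNA was column-purified and treated with DNase, and amplified antisense RNA was labelled with biotin. The labels place 3 arrays in the control group and 3 in the group exposed to GYY4137, a compound that releases hydrogen sulfide (H2S) slowly. The protocol text, which is the same for all 6 arrays, gives 100 uM GYY4137 for 48 h in liquid medium and then 12 h on plates. The length of any mock exposure of the controls is therefore not given in the sources used here.

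The values deposited by the authors are 1 per probe set and array and were made with GCRMA, which corrects background by probe sequence, normalizes arrays and summarises probes, per the submitters' processing notes. The deposited values are read here as log2, because they run from 1.88 to 13.3 over the 6 arrays, the range that GCRMA writes. The software version and any further filter are not given in the sources used here. Replicates were deposited separately. No further normalization was applied.

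The array carries 22625 probe sets, of which 77 are Affymetrix controls and were left out of the tests. Gene names came from the platform annotation, updated by gene number through a RefSeq gene table of assembly WBcel235, which was used only for names and for which genes neighbour each other. There were 20810 probe sets with 1 gene symbol, 843 with several and 972 with none, controls included, and 20702 of those with 1 symbol matched the gene table. No gene was named from a probe set with several symbols. Probe sets ending in _s_at or _x_at can bind transcripts of more than 1 gene, and genes measured on these are open to signal from close relatives.

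A probe set was tested when its value was above 4 on the log2 scale on 3 or more of the 6 arrays, whichever group they were in, which left 8053. GYY4137 minus control was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend, two-sided), and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Each ± given with a log2 difference is the standard error from this fit, with 3 arrays per group. For gene lists, each gene was represented by its probe set with the highest mean over the 6 arrays, which gave 6230 genes.

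The 39 gene lists, the tests, the settings to vary and the rule for genes named in the text were fixed before the data were examined. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which asks whether members rank higher or lower than the other genes, with Benjamini-Hochberg adjustment over the 39 lists. Camera with an estimated correlation and fry were run beside it. The fry test asks whether members move 1 way on balance, and its mixed form asks whether they change in either direction; neither compares the list with other genes. Members also received a p adjusted over the list alone.

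The named genes were, per direction, up to 12 with the largest change among those with adjusted p under 0.05, no overlap between groups, a probe set for 1 gene and a mean of at least 6. Where fewer than 12 passed, the genes with the smallest p in that direction followed, up to 8 in all. Up to 4 members per list, those with the smallest p, were added, as were sqrd-1, ethe-1, cth-1, cth-2, cysl-2, rhy-1, sod-3, mtl-1, hsp-16.2, hsp-6, hsp-4, gst-4, daf-16, hif-1, skn-1 and hsf-1, whatever their values. Other genes named are said to be chosen after their values were seen.

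The procedure was tested on simulated data for the same comparison, with 200 of 8053 probe sets changed in each of 20 simulations. In these simulations it recovered 73.2% of 2-fold and 96.4% of 4-fold changes, and 4.72% of its calls were false. These rates describe the simulated noise only. They were not tested with an array that stood apart, as GYY4137 replicate 3 did in the data, and need not hold for the data. A list of proteasome genes shifted by 0.5 on the log2 scale was called in 20 of 20 simulations. The simulated noise was independent between genes, so the list result says nothing about correlated genes.

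The alternatives were no filter, a filter at 6, quantile normalization, median centring, an intensity trend, array weights, the replicate number as a block, each array left out in turn, other thresholds, counting by gene, an estimated correlation and the mean over a gene's probe sets. The number of arrays limits the precision, and nothing in the labels says that replicates were separate cultures. P-values therefore measure only the spread between these samples, which may be technical. Arrays with a value below the floor give no firm level for a gene.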

Results

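The study compared the transcriptome of wild-type worms with that of worms exposed to GYY4137, in a series whose title concerns H2S and lifespan. Each of the 6 arrays had between 7723 and 8050 probe sets above the log2 floor of 4. The median over the tested probe sets lay between 5.66 and 5.85 on the 6 arrays.

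GYY4137 replicate 3 stood apart from the other 5 arrays. Its Pearson correlations with them, across probe sets, ran from 0.940 to 0.965, against 0.979 to 0.993 among the other 5. The first principal component, with 65.9% of the variance, set this array at 40.1, and the other 5 lay between -14.8 and 2.84. On the second component, with 16.6%, the controls lay between -9.18 and -3.64 and GYY4137 replicate 3 at -7.46, with the other GYY4137 arrays on the positive side.

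**Figure D1:**
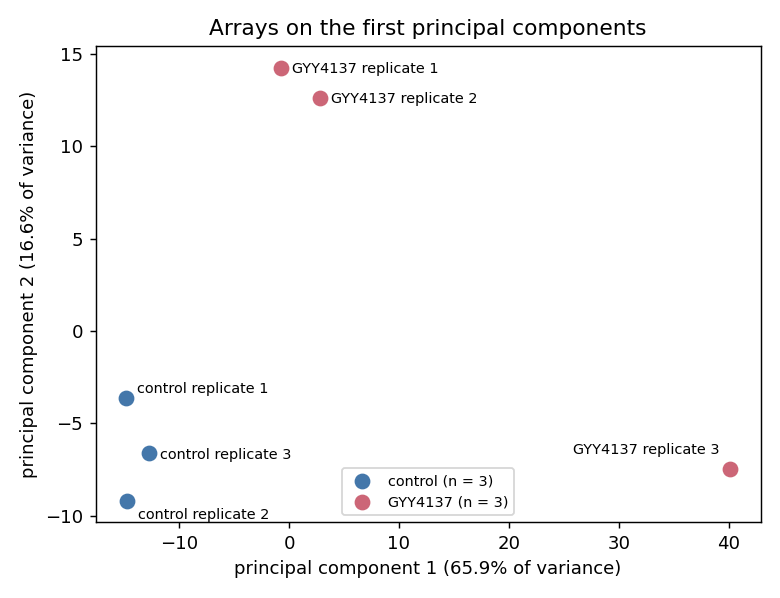
Positions of the 3 control and 3 GYY4137 arrays on the first principal components of the tested log2 values, with the share of variance of each component on its axis (65.9% and 16.6%). Each point is 1 array, and GYY4137 replicate 3 lies at 40.1 on the first component.

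Sysm-1, a reporter gene of the PMK-1 immune pathway, rose after GYY4137, from a log2 value of 4.00 ± 0.02 to 6.50 ± 0.09 (SD, n = 3 per group, limma adjusted p = 0.000219). The control value lay at the floor of 4, so the size of this rise is uncertain. It had the largest rise among called probe sets for 1 gene and was chosen after its values were seen. The gene dod-22, which is held down by active DAF-16, rose by 2.19 ± 0.17 (4.56-fold, adjusted p = 0.00343). The C-type lectin genes clec-41, clec-85 and clec-62 rose by 1.41 ± 0.24, 1.32 ± 0.22 and 1.32 ± 0.14. The protease gene cpr-4, a cathepsin B relative, rose by 1.13 ± 0.12 from an already high control value of 9.29 ± 0.16 (SD). The collagen genes col-2 and col-41 rose by 1.68 ± 0.20 and 1.31 ± 0.23, and the less described genes C50F7.5, F53A9.1, F53A9.6, Y53F4B.45 and Y43C5A.3 by 1.87 ± 0.22, 1.42 ± 0.12, 1.34 ± 0.12, 1.26 ± 0.15 and 1.12 ± 0.14. Of the raised genes, clec-41, clec-62, col-2, col-41, Y53F4B.45 and F53A9.6 were read on probe sets that can bind related transcripts. Sysm-1, dod-22 and F53A9.1 were called whichever array was left out. F53A9.6 was not called without control replicate 1, and col-2 not without control replicate 1 or 2. Each of the other genes named here lost its call without control replicate 1 or 2 and, except cpr-4 and Y53F4B.45, without control replicate 3. Without GYY4137 replicate 2 the calls of C50F7.5, clec-41, clec-85, col-41, Y53F4B.45, cpr-4 and Y43C5A.3 ended, and without GYY4137 replicate 1 those of clec-41, clec-85 and col-41.

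Fewer genes fell. C30G12.2 fell by 2.02 ± 0.12 on the log2 scale (adjusted p = 0.000816), the largest fall among the named genes. Abu-15, abu-6 and abu-8, which belong to a family expressed in the pharynx and first described in worms with a blocked unfolded protein response, fell by 1.87 ± 0.23, 1.65 ± 0.16 and 1.49 ± 0.23. All 3 were read on probe sets that can bind related transcripts. The acid sphingomyelinase gene asm-3 fell by 1.81 ± 0.20, F42A10.7 by 1.38 ± 0.14, the short-chain dehydrogenase gene dhs-26 by 1.31 ± 0.13 and the collagen gene col-81 by 0.72 ± 0.13. The GYY4137 means of dhs-26 and asm-3, 2.90 and 3.07, lay under the floor. Asm-3 and col-81 were also read on probe sets that can bind related transcripts. C30G12.2 and dhs-26 were called whichever array was left out. Without control replicate 1 the calls of the other 6 ended. Those of abu-15, abu-8 and col-81 ended without control replicate 2, and those of abu-15, abu-8, asm-3, F42A10.7 and col-81 without control replicate 3. A lost call did not mean a lost fall: without control replicate 1, abu-15, abu-6 and abu-8 were at -1.99, -1.71 and -1.61. Asm-3, F42A10.7 and col-81 were then at -1.63, -1.34 and -0.72. The calls of abu-15, abu-8, asm-3 and col-81 also ended without GYY4137 replicate 2, and those of abu-8 and col-81 without GYY4137 replicate 1.

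**Figure D2:**
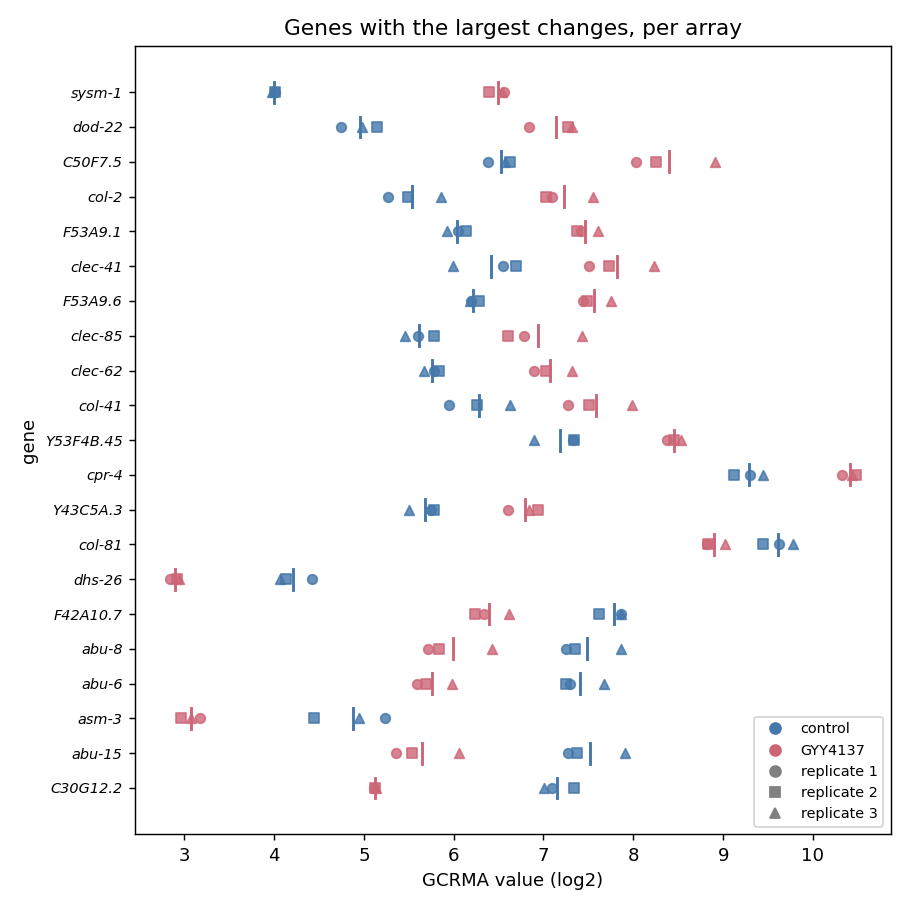
GCRMA values (log2) of the named genes with the largest changes, dhs-26 and asm-3 chosen by smallest p, and sysm-1, on each array. Points are arrays (3 control, 3 GYY4137), shapes mark replicates and bars mark group means; sysm-1 moved from 4.00, a control value at the floor that leaves the size of its rise uncertain, to 6.50, and C30G12.2 from 7.15 to 5.13.

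In all, limma called 121 of 8053 probe sets, 88 raised and 33 lowered, of which 48 and 22 changed at least 2-fold. By gene, 73 were raised and 20 lowered among those with a probe set of their own. The groups did not overlap for 2333 of the 8053 tested probe sets, where chance gives 10%; these include the 121, which the test selects for separation. An unadjusted p under 0.05 was reached by 1427. The count changed with each array left out. It was 12, 21 and 19 without control replicate 1, 2 or 3, and 63 and 27 without GYY4137 replicate 1 or 2. Without GYY4137 replicate 3 it rose to 381 (245 raised, 136 lowered), including all 121. It was 33 with no filter, 80 with a floor of 6 and 1389 with array weights. With array weights all 16 lists that camera called below held called members, among them 21 raised neuropeptide and 13 raised major sperm protein genes. With no filter 1 C-type lectin and 1 gene lowered by active DAF-16 were raised, 1 fatty acid synthesis gene and 1 short-chain dehydrogenase were lowered, and the infection-response, neuropeptide, collagen, intestine, muscle and pharynx lists held 0 called members. Of the 121, 11 kept their call in all 6 leave-outs, among them sysm-1, dod-22, C30G12.2, F53A9.1 and dhs-26.

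Antimicrobial and infection-response genes were raised as a list, with 8 of 32 tested members raised, 0 lowered and 24 not passing (median 0.30, camera adjusted p = 7.13e-08, and adjusted p = 0.227 with an estimated correlation). Adjusted over the list alone, 15 were raised and 1 was lowered. With no filter, over 68 members, the median was 0.08 and camera still passed (adjusted p = 4.24e-05), with 0 raised; 3 were raised with a floor of 6 and 17, with 1 lowered, with array weights. The caenacin gene cnc-6 rose by 1.76 ± 0.25, the infection-response gene irg-5 by 1.30 ± 0.17, the saposin-like gene spp-18 by 0.98 ± 0.15 and the lysozyme gene lys-2 by 0.92 ± 0.13. The control means of cnc-6 and irg-5, 2.55 and 3.58, lay under the floor, so the sizes of these rises are uncertain. Without GYY4137 replicate 3 the count of raised members was again 8, but it was 1, 0 and 0 without control replicate 1, 2 or 3, and 2 and 0 without GYY4137 replicate 1 or 2. On GYY4137 replicate 3 the list's median lay 0.13 above the mean of the other GYY4137 arrays.

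C-type lectins, a family of sugar-binding proteins, were raised too (median 0.37, camera adjusted p = 1.04e-07, and adjusted p = 0.396 with an estimated correlation). Of 30 members 5 rose, 0 fell and 25 did not pass, and adjusted over the list alone 10 were raised and 1 was lowered. With no filter, over all 220 members on the array, the median was 0.01 (adjusted p = 0.0117) and 1 was raised, and with array weights 14 were raised and 2 lowered. Besides the 3 named above, clec-48 rose by 1.04 ± 0.12. Leaving out any control array left 0 raised members, leaving out GYY4137 replicate 1 or 2 left 2, and leaving out GYY4137 replicate 3 gave 9, with 1 lowered. The list stood 0.28 higher on GYY4137 replicate 3 than on the other GYY4137 arrays, and its median without that array was 0.24.

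Genes that active DAF-16, the FOXO factor of the insulin pathway, keeps low were raised (median 0.62, camera adjusted p = 2.63e-05, and adjusted p = 0.305 with an estimated correlation). Of 10 members 4 rose, 0 fell and 6 did not pass, and adjusted over the list alone 6 were raised. The median was 0.10 with no filter, where camera still passed (adjusted p = 6.83e-05) and 1 member was raised, and 0.40 with array weights. Beside dod-22, the insulin-like peptide gene ins-7 rose by 1.24 ± 0.15, dod-24 by 0.93 ± 0.12 and dod-23 by 0.81 ± 0.13. Of the members tested, only dod-22 passed without any single control array or without GYY4137 replicate 2. Without GYY4137 replicate 1, 3 members passed, and without GYY4137 replicate 3, 5. A probe set with several symbols, among them a gene fixed for this list, was not used. It rose by 3.12 (limma adjusted p = 0.000312) and was called in all 6 leave-outs. Genes that active DAF-16 raises also ranked higher (median 0.25, camera adjusted p = 0.00725, and adjusted p = 0.305 with an estimated correlation), with 0 of 13 members passing and 1, icl-1 of the glyoxylate cycle (0.65 ± 0.15), raised when adjusted over the list alone. Without GYY4137 replicate 3, 2 members passed, and with no filter on low values the list did not (median 0.09, adjusted p = 0.0603); with array weights the median was 0.15 and 4 members were raised. Other members with the smallest p were ftn-1 (0.49 ± 0.15), lys-7 (0.29 ± 0.10) and lea-1 (0.36 ± 0.13). The transcript of daf-16 itself differed by -0.10 ± 0.12 (adjusted p = 0.656), and by -0.17, -0.04 and -0.04 without control replicate 1, control replicate 3 or GYY4137 replicate 2.

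Neuropeptide and insulin-like peptide genes had the smallest list p at the main settings (median 0.31, camera adjusted p = 3.29e-09, and adjusted p = 0.121 with an estimated correlation). Major sperm protein genes had a smaller one with no filter, a floor of 6 or an intensity trend. The same held without control replicate 2 or GYY4137 replicate 1. Of the 44 neuropeptide and insulin-like peptide genes 1 rose, ins-7, 0 fell and 43 did not pass. Adjusted over the list alone 12 were raised. With no filter the median was 0.12 (adjusted p = 4.34e-08); 3 were raised under quantile normalization or median centring, and 0 with a floor of 6. The FMRFamide-like genes flp-15, flp-5 and flp-19 differed by 0.74 ± 0.15, 0.66 ± 0.13 and 0.58 ± 0.12 without passing. Ins-7 kept its call without GYY4137 replicate 1 and was not called without control replicate 1, 2 or 3 or GYY4137 replicate 2, and 7 members were called without GYY4137 replicate 3. Neuron markers did not pass (0 of 8 members, camera adjusted p = 0.225); the peptide-processing genes egl-3 and egl-21 differed by 0.45 ± 0.16 and 0.36 ± 0.15, the latter by 0.22 without GYY4137 replicate 3.

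Metal-responsive genes ranked higher (median 0.34, camera adjusted p = 0.000589, and adjusted p = 0.227 with an estimated correlation), with 7 of 7 members above control, none passing over all genes, and 2 raised when adjusted over the list alone. These were cdr-4, a cadmium-responsive gene (0.59 ± 0.15), and the ferritin gene ftn-1, and 2 members passed over all genes without GYY4137 replicate 3. Fatty acid breakdown and lipase genes ranked higher (median 0.09, camera adjusted p = 0.0180, and adjusted p = 0.396 with an estimated correlation), with 0 of 21 passing and 4 raised over the list alone: lipl-5 (0.71 ± 0.18), icl-1, the carnitine palmitoyltransferase gene cpt-4 (0.60 ± 0.17) and the acyl-CoA synthetase gene acs-2 (0.56 ± 0.12). Fatty acid synthesis and desaturation genes ranked lower (median -0.17, camera adjusted p = 0.0180, and adjusted p = 0.460 with an estimated correlation), with 0 of 14 passing and 3 lowered over the list alone. The desaturase gene fat-3 differed by -0.66 ± 0.13 and the elongase genes elo-2, elo-5 and elo-6 by -0.59 ± 0.13, -0.49 ± 0.16 and -0.45 ± 0.10. The synthesis list did not pass without control replicate 2 (adjusted p = 0.0665) or without GYY4137 replicate 1 (adjusted p = 0.0528), and the breakdown list did not pass when no filter was applied (median 0.02, adjusted p = 0.388). The breakdown median was 0.15 without GYY4137 replicate 1, 0.16 under median centring and 0.04 with array weights, and the synthesis median was -0.09 under median centring and -0.05 with no filter. Of the synthesis genes 1 was lowered with no filter or a floor of 6, 2 with an intensity trend and 3 with array weights. Without GYY4137 replicate 3, 2 breakdown genes were raised and 3 synthesis genes lowered over all genes.

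Sperm genes ranked higher after GYY4137 and oocyte genes lower. Major sperm protein genes ranked higher (median 0.34, camera adjusted p = 9.66e-09, and adjusted p = 0.460 with an estimated correlation), with 23 of 23 members above control and none passing over all genes or over the list alone. Their estimated inter-gene correlation was 0.83, the 4 named here were read on probe sets that can bind related transcripts, and msp-142, msp-64, msp-152 and msp-33 differed by 0.73 ± 0.19, 0.56 ± 0.16, 0.49 ± 0.16 and 0.46 ± 0.12. Other sperm genes ranked higher (median 0.45, camera adjusted p = 0.000399, and adjusted p = 0.396 with an estimated correlation), with 0 of 12 passing and 6 raised over the list alone, among them ssq-2 (0.91 ± 0.21), ssq-3 (0.54 ± 0.15), ssp-16 (0.50 ± 0.15) and nspd-2 (0.37 ± 0.10). On GYY4137 replicate 3 the major sperm protein list stood 0.40 and the other sperm list 0.42 above the mean of the other GYY4137 arrays; without it the list medians were 0.24 and 0.29, both lists passed, and 1 and 2 members were raised. With no filter the other sperm median was 0.02 over 26 members (adjusted p = 0.0190). Oocyte and eggshell genes ranked lower (median -0.19, camera adjusted p = 0.00555, and adjusted p = 0.415 with an estimated correlation), with 0 of 23 passing; egg-3, spn-4, mex-3 and egg-1 differed by -0.52 ± 0.12, -0.51 ± 0.13, -0.48 ± 0.13 and -0.33 ± 0.11, and 1 member was lowered without GYY4137 replicate 3, on which the list stood at -0.12 against the other GYY4137 arrays. The oocyte median was -0.11 under median centring. General germline genes did not pass (camera adjusted p = 0.184, 0 of 25 members; syp-1 -0.57 ± 0.27, and -0.25 without GYY4137 replicate 3, glh-4 -0.25 ± 0.10), nor did yolk protein genes (adjusted p = 0.546, 0 of 5; vit-1 -0.41 ± 0.12). With no filter the germline list passed, ranking lower (adjusted p = 0.00144). Histone genes ranked higher (median 0.20, camera adjusted p = 0.000289, and adjusted p = 0.460 with an estimated correlation), with 22 of 24 members above control, none passing, and his-61 and his-37 at 0.40 ± 0.17 and 0.39 ± 0.15; the list stood 0.25 higher on GYY4137 replicate 3, and without that array its median was 0.13 and his-61 was at 0.22. With array weights the histone median was 0.11. The labels give L4 larvae, while yolk and eggshell genes, which adults express, had high control values, such as 12.8 for vit-4 and 9.08 for egg-1; the stage at harvest is not settled by the sources used here.

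Collagen genes, which encode the main cuticle proteins, changed in both directions. Of 89 collagen genes 4 rose, 1 fell and 84 did not pass, and adjusted over the list alone 11 were raised and 11 lowered; as a list they did not rank higher or lower (camera adjusted p = 0.254), while fry's mixed test passed (adjusted p = 0.000289). Col-183 rose by 1.26 ± 0.19 and dpy-8 by 1.03 ± 0.17, beside col-2, col-41 and col-81 above. These counts use 1 probe set per gene and leave out those with several symbols. Called collagen probe sets with several symbols fell by 1.57 and 1.56 (limma adjusted p = 0.00609 and 0.0410). A further dpy-2 probe set, chosen after its values were seen, rose by 0.79 (limma adjusted p = 0.0363). None of these was called without control replicate 1 or 3. The control means of col-183 and of the moulting gene mlt-9, 3.76 and 3.55, lay under the floor. Moulting-cycle genes ranked higher (median 0.51, camera adjusted p = 0.000178, and adjusted p = 0.494 with an estimated correlation), with 0 of 20 passing, and 9 raised and 3 lowered when adjusted over the list alone. Mlt-9 and the collagen gene sqt-1 differed by 1.05 ± 0.23 and 0.91 ± 0.20, and the ground-like gene grl-21 and the moulting regulator nhr-23 by -0.93 ± 0.23 and -0.81 ± 0.19. GYY4137 replicate 3 was 0.56 above the other GYY4137 arrays for the moulting list, whose median without it was 0.27, and 0.29 for the collagens. Without it the collagen counts were 9 raised and 12 lowered; without control replicate 1 or 2 they were 0 and 0, without control replicate 3 or GYY4137 replicate 2 only col-2 passed, and without GYY4137 replicate 1 there were 3 raised and 0 lowered. The counts were 6 and 0 under median centring, 5 and 2 under quantile normalization, 5 and 4 with an intensity trend, 3 and 3 with a floor of 6, and 17 and 19 with array weights. The collagen list itself ranked higher without control replicate 3 (adjusted p = 0.0063) and without GYY4137 replicate 1 (0.0249), and 2 moulting genes were raised and 3 lowered without GYY4137 replicate 3. Adult cuticle genes (camera adjusted p = 0.128, 0 of 8 passing; col-63 0.63 ± 0.21, bli-2 0.54 ± 0.17) and epidermis markers (adjusted p = 0.415, 0 of 11; wrt-2 0.75 ± 0.25) did not pass, and the epidermis list stood 0.42 and the adult cuticle list 0.24 higher on GYY4137 replicate 3. Adult cuticle genes passed, ranking higher, without control replicate 3 (adjusted p = 0.0184), without GYY4137 replicate 1 (0.0368) and with array weights (0.0434). The list leaves out the probe set above that fell by 1.57, although both of its symbols are adult cuticle genes of this list.

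Body wall muscle and pharynx markers ranked lower than other genes at the preset correlation, with few single members passing. Of 16 body wall muscle markers 16 lay below control, 1 fell and 15 did not pass (median -0.25, camera adjusted p = 8.65e-05, and adjusted p = 0.436 with an estimated correlation); adjusted over the list alone 3 were lowered. The titin gene ttn-1 fell by 1.28 ± 0.17. The sarcomere genes unc-89 and myo-3 differed by -0.71 ± 0.14 and -0.55 ± 0.14. Another unc-89 probe set, not used for the list, was called (-0.66, limma adjusted p = 0.0461). Of the leave-outs, it kept this call only in that of GYY4137 replicate 3. Of 10 pharynx markers 2, abu-6 and abu-8, fell and 8 did not pass (median -0.27, camera adjusted p = 0.00137, and adjusted p = 0.494 with an estimated correlation), and 4 were lowered over the list alone. Abu-11 differed by -0.76 ± 0.23 and the troponin gene tnt-4 by -0.73 ± 0.17. Ttn-1 was called without GYY4137 replicate 1 but not without any single control array or GYY4137 replicate 2, and 5 muscle markers were called without GYY4137 replicate 3. Abu-6 was called in each leave-out but that of control replicate 1, abu-8 only without GYY4137 replicate 3, where 4 pharynx markers were called. On GYY4137 replicate 3 the muscle list stood 0.24 and the pharynx list 0.35 above the other GYY4137 arrays, opposite to the lists' direction. The pharynx median was -0.46 without that array and -0.16 without control replicate 3, and -0.03 with no filter, over 20 members (adjusted p = 0.0253). Intestine markers ranked slightly higher (median 0.09, camera adjusted p = 0.0180, and adjusted p = 0.305 with an estimated correlation), with 1 of 17, the protease gene cpr-3, raised by 1.28 ± 0.16 from a control mean of 3.97, under the floor, 0 lowered and 16 not passing. The intestine median was 0.15 without control replicate 1 or 3 and 0.19 without GYY4137 replicate 1, and 0.16 under median centring. The intestine list did not pass without GYY4137 replicate 3 (adjusted p = 0.110), after quantile normalization (median 0.15, 0.0733), with a floor of 6 (median 0.14, 0.1) or with array weights (0.0846), and cpr-3 was not called without any single control array. Cpr-3 was read on a probe set that can bind related transcripts. The phosphatase gene pho-1, also of the intestine list, differed by -0.55 ± 0.17.

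**Figure D3:**
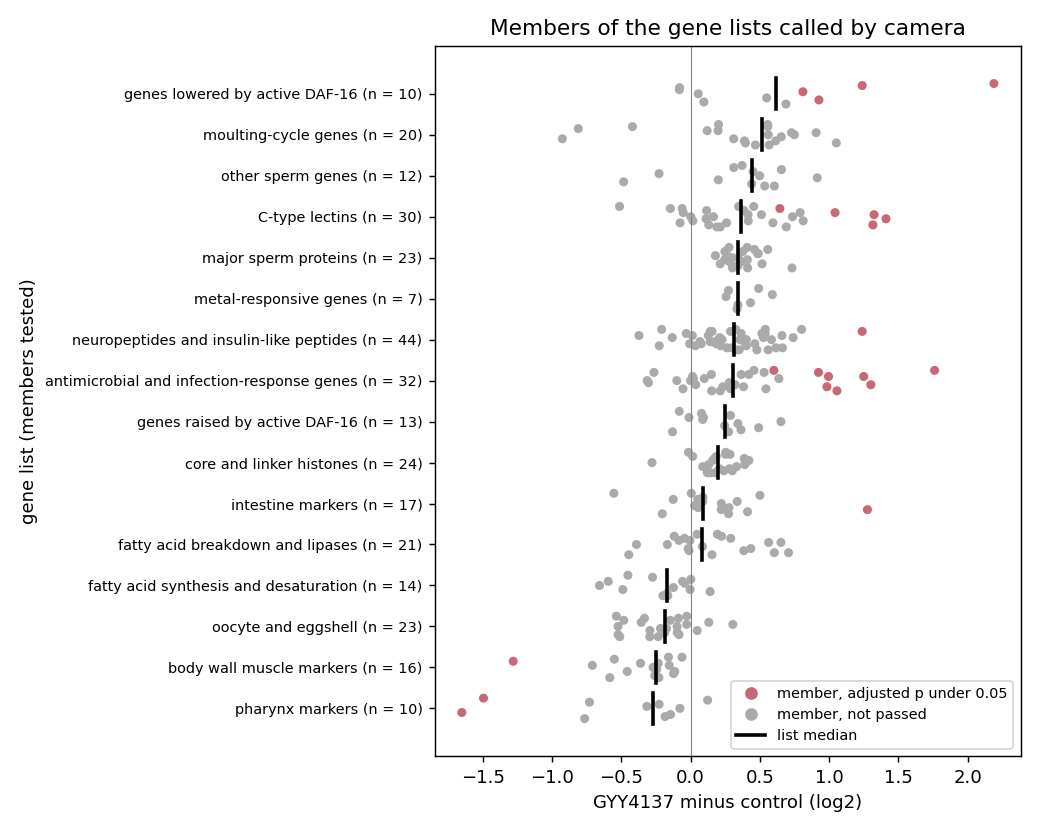
Log2 differences, GYY4137 minus control, of the members of the 16 lists called by camera, with the number of members tested. Each point is 1 gene, coloured where its adjusted p was under 0.05, and the bar is the list median, from -0.27 for pharynx markers to 0.62 for genes lowered by active DAF-16.

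Genes of sulfide and cysteine metabolism, which include enzymes that make and oxidize H2S, did not pass as a list or singly in limma (0 of 13 members over all genes or over the list alone, camera adjusted p = 0.789). The list stood 0.20 higher on GYY4137 replicate 3 than on the other GYY4137 arrays. The cystathionine gamma-lyase genes cth-1 and cth-2 differed by -0.39 ± 0.14 (adjusted p = 0.238) and -0.19 ± 0.17, gcs-1 and cbl-1 by -0.53 ± 0.18 and -0.38 ± 0.13, and cysl-2 by 0.64 ± 0.18 (adjusted p = 0.150). Gcs-1 was at -0.34 and cth-2 at -0.36 without GYY4137 replicate 3, and cth-2 at -0.05 without GYY4137 replicate 2. The sulfide quinone oxidoreductase gene sqrd-1 and the persulfide dioxygenase gene ethe-1 lay under the floor in both groups, at 3.68 ± 0.17 and 3.31 ± 0.18 (SD) in controls and 3.27 ± 0.20 and 3.33 ± 0.05 after GYY4137. Fry's mixed test, which asks for change in either direction, passed for this list (adjusted p = 0.00964), and its directional form did not (adjusted p = 0.803). The HIF-1 and hypoxia list did not pass (0 of 8, camera adjusted p = 0.118), while fry's mixed test did (adjusted p = 0.0147); hif-1 and phy-2 differed by 0.23 ± 0.12 and 0.20 ± 0.11, and rhy-1 lay under the floor at 3.76 ± 0.11 and 3.56 ± 0.02 (SD).

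Stress-response lists did not pass camera or fry's directional test either. Heat shock genes gave 0 of 15 (camera adjusted p = 0.546, and 0.039 ranking lower with no filter), with hsp-17 at 0.73 ± 0.20, hsp-70 at -0.71 ± 0.31, hsp-16.2 at -0.45 ± 0.24 and hsf-1 at -0.14 ± 0.10. Hsp-70 was at -0.36 and hsp-16.2 at -0.16 without GYY4137 replicate 3. The mitochondrial unfolded protein response gave 0 of 10 (adjusted p = 0.629), with hsp-6 at -0.04 ± 0.12 and dnj-10 at -0.57 ± 0.18. The endoplasmic reticulum response gave 0 of 19 (adjusted p = 0.254, and 0.00679 ranking lower with no filter), with hsp-4 at -0.01 ± 0.13, ire-1 at -0.52 ± 0.15 and ckb-2 at 0.52 ± 0.17. Antioxidant enzymes gave 0 of 15 (adjusted p = 0.254), with prdx-6 at 0.27 ± 0.11, and the superoxide dismutase gene sod-3 lay under the floor at 2.57 ± 0.03 and 2.52 ± 0.08 (SD). SKN-1 and phase 2 genes gave 0 of 11 (adjusted p = 0.697, and 0.0475 in fry's mixed test, which passed), with skn-1 at -0.10 ± 0.11, gst-4 at 0.20 ± 0.22 and gst-10 at -1.02 ± 0.22, the last lowered when adjusted over the list alone. The other stress lists had no member passing over the list alone. Without GYY4137 replicate 3, 1 member each was raised among the heat shock, endoplasmic reticulum and HIF-1 lists, and 1 each lowered among the SKN-1 and antioxidant lists. The metallothionein gene mtl-1 differed by 0.34 ± 0.18, and by 0.22 without GYY4137 replicate 1. The differences of hsp-6 and hsp-4 were positive under median centring and without GYY4137 replicate 1 (0.05 and 0.02). That of hsp-4 was also positive without control replicate 1 (0.003) or 2 (0.08). Without control replicate 3 hsp-4 was at -0.11 and without GYY4137 replicate 3 hsp-6 was at -0.11. Skn-1 was at -0.01 without control replicate 2, and gst-4 at 0.33, -0.01 and 0.05 without control replicate 1, control replicate 3 or GYY4137 replicate 3.

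Detoxification families held 1 call each among the glucuronosyltransferases and short-chain dehydrogenases: ugt-26 fell by 1.06 ± 0.16 (1 of 22 lowered and 4 over the list alone, camera adjusted p = 0.0961) and dhs-26 fell as above (1 of 14, also over the list alone, camera adjusted p = 0.862). Fry's mixed test passed for both lists (adjusted p = 0.00291 and 0.00125). Ugt-26 was called only with all arrays or without GYY4137 replicate 3, and not without any other single array, and was not called with no filter. Glutathione S-transferases (0 of 17 and, over the list alone, gst-10 lowered; adjusted p = 0.114), cytochrome P450 genes (0 of 11, adjusted p = 0.254) and nuclear hormone receptors (0 of 20, adjusted p = 0.789) did not pass, and the glutathione S-transferases stood 0.41 higher on GYY4137 replicate 3. The transferase list ranked higher without control replicate 1 (adjusted p = 0.0454), GYY4137 replicate 1 (0.0403) or GYY4137 replicate 2 (0.03), but not without GYY4137 replicate 3 (adjusted p = 0.811). Insulin, TOR and AMPK regulators gave 0 of 23 (adjusted p = 0.135), with daf-18 at -0.56 ± 0.21, and -0.34 without GYY4137 replicate 3, and ranked lower with no filter (adjusted p = 0.039) and without control replicate 3 (0.0492). Respiratory chain genes (0 of 35, adjusted p = 0.188), glycolysis genes (0 of 17, adjusted p = 0.695), ribosomal protein genes (0 of 74, adjusted p = 0.0725) and proteasome genes (0 of 33, adjusted p = 0.0811) did not pass, with 0 members passing over the list alone. The respiratory chain list stood 0.28, the glycolysis list 0.22 and the proteasome list 0.17 higher on GYY4137 replicate 3. The respiratory chain list ranked higher without GYY4137 replicate 1 (adjusted p = 0.0386), and its direction was down without GYY4137 replicate 3 (adjusted p = 0.666) and with array weights (0.784). The proteasome list ranked higher without control replicate 1 (adjusted p = 0.039) or GYY4137 replicate 2 (0.0242), and the ribosomal list under median centring (0.0108), with an intensity trend (0.00666), with no filter (0.0247) and with the mean over probe sets (0.0367).

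Of the 39 lists camera thus called 16, 12 ranked higher and 4 lower. With an estimated correlation 0 were called, the lowest adjusted p being 0.121, and 6 had an unadjusted p under 0.05. Fry called 5 lists in 1 direction (infection-response, both DAF-16 lists, metal-responsive and neuropeptide genes, each at adjusted p = 0.0125) and 19 in its mixed form. Without GYY4137 replicate 3, camera called 11 raised and 4 lowered lists, 15 of them shared with the full set and alike in direction. For 3 lists that did not pass, the median was below 0 while the mean and camera's direction were above it: sulfide metabolism (-0.07 and 0.01), where fry's direction was also down, the mitochondrial unfolded protein response and glycolysis. These signs are not firm: the sulfide median was 0.08 and 0.04 without GYY4137 replicate 1 or 3, -0.02 without control replicate 1, -0.05 without GYY4137 replicate 2, -0.20 with a floor of 6, and nearer 0 with no filter, array weights or either normalization. Camera's direction for it was down without GYY4137 replicate 3, with no filter, a floor of 6 or array weights. The mitochondrial median was above 0 without control replicate 2 or GYY4137 replicate 1, with a floor of 6 or array weights and under either normalization, and camera's direction was down with no filter. The glycolysis median was above 0 without control replicate 2, GYY4137 replicate 1 or GYY4137 replicate 2, with a floor of 6 or array weights and under median centring, and camera's direction was down with no filter, under quantile normalization and without GYY4137 replicate 3.

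Among named genes that did not pass, array weights moved several by over 1.5 times, besides hsp-6 and hsp-4: cth-2 to -0.43, syp-1 to -0.35, ire-1 to -0.32, elo-5 to -0.30, mex-3 to -0.30, dnj-10 to -0.29, hsp-70 to -0.28, daf-18 to -0.26, hsp-16.2 to -0.12, hsf-1 to -0.08, skn-1 to -0.06, lea-1 to 0.18, prdx-6 to 0.18, his-61 to 0.22, ssp-16 to 0.30 and gst-4 to just below 0. Median centring moved cth-2 to -0.12, hsf-1 to -0.07, daf-16 to -0.03 and skn-1 to -0.02, and quantile normalization moved hsf-1 to -0.07 and daf-16 to -0.05.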

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

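The settings reported here were chosen before the data were examined. All 121 called probe sets kept the sign of their difference, and an unadjusted p under 0.05, wherever they were tested. The count of calls was 33 (21 raised, 12 lowered) with no filter on low values, where more probe sets were tested, and 80 (58 raised) with a floor of 6, where 56 of the 121 were tested and all 56 kept their call. It was 267 at adjusted p under 0.1 and 70 at 2-fold or more. Array weights gave 1389 (706 raised, 683 lowered), with weight 0.143 for GYY4137 replicate 3 and 4.82 for replicate 2; raised calls were then 50.8% of all. Leaving out 1 array at a time, the count ran from 12 to 381, raised calls from 8 to 245 and lowered calls from 4 to 136. Each leave-out drops 1 array, yet only that of GYY4137 replicate 3 raised the count, to 381, and kept all 121. The smaller number of arrays alone therefore does not account for this range, and the cause was not tested. Quantile normalization kept 115 of the 121, median centring 116 and no filter 25.

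With the replicate number as a block the count was 73 (51 raised), and 63 of the 121 kept their call. Raised members were then 2 infection-response genes, 2 C-type lectins, 2 genes lowered by active DAF-16 and 1 moulting-cycle gene. The neuropeptide and insulin-like list and the intestine list each held 1 raised member. Of the collagens 5 were raised and 0 lowered. Of the muscle markers 0 were lowered, so ttn-1 lost its call. Same-numbered arrays shared little: their deviations from the group means correlated across probe sets at 0.108, -0.016 and 0.0513 for numbers 1, 2 and 3, and not every array correlated best with its own number. The block changed no list call.

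Camera called 8 lowered lists without a filter, and 0 raised and 0 lowered with an estimated correlation. Over the leave-outs, raised lists ran from 11 to 16 and lowered lists from 3 to 5. With a floor of 6 the HIF-1, metal-responsive, cytochrome P450 and nuclear hormone receptor lists had too few members to test. Signal near background limits genes such as sqrd-1, ethe-1, rhy-1 and sod-3.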

Other observations

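The name-family test, the test of neighbouring genes, and the tests of RNA quality, intestine share, replicate 3 alone and developmental timing below were chosen after the results were seen, as was the use of oocyte genes for the germline share, and the bound for timing was changed after its correlation was seen. Among 166 families of genes that share a name prefix and had at least 5 tested members, 3 were enriched among called genes by Fisher's exact test (one-sided, Benjamini-Hochberg adjusted). The abu family had 3 of 7 members lowered (adjusted p = 0.000163), the clec family 5 of 30 raised (adjusted p = 0.00362) and the dod family 3 of 8 raised (adjusted p = 0.00688). The same 3 families passed among 253 families when at least 4 members were required. The clec and dod families overlap lists already described, and abu probe sets can bind related transcripts. Fewer members of all 3 were called when any array but GYY4137 replicate 3 was left out. All called probe sets kept their sign in each leave-out. Lost calls were not told apart from the smaller number of arrays with GYY4137 replicate 3 still among them. The abu, clec and dod members called were 0, 0 and 1 without control replicate 1, and 1, 0 and 1 without control replicate 2 or 3. They were 2, 2 and 2 without GYY4137 replicate 1, 1, 2 and 1 without GYY4137 replicate 2, and 4, 9 and 4 without GYY4137 replicate 3.

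Called genes lay near each other more often than in random draws: 7 pairs of 92 called genes were within 3 genes of one another, against a mean of 1.76 and a 95th percentile of 4 in 10000 random draws (one-sided permutation p = 0.0037). Among genes called without control replicate 1 there were 0 such pairs, without control replicate 2 or 3 or GYY4137 replicate 2 there was 1, without GYY4137 replicate 1 there were 2, and without GYY4137 replicate 3, where more genes were called, 30. In all 7 pairs of the full set both genes changed the same way. The pairs join F53A9.1, F53A9.6, F53A9.8 and F53A9.9 (raised by 1.42, 1.34, 1.07 and 0.75), C50F7.5 and F33D4.6 (1.87 and 0.81), and abu-15 and abu-6. All pairs but the last 2 named came from the F53A9 genes, so the pairs were not independent. The excess over random draws thus rested on this 1 cluster. Relatedness of sequence was not tested apart from position: F53A9.6, F53A9.8, F33D4.6 and the abu genes were read on probe sets that can bind related transcripts.

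GYY4137 replicate 3 lay apart from the other arrays. Degraded RNA would lower the signal at the 5' relative to the 3' end of control transcripts, and this array was below all others for 0 of 3 (actin, GAPDH, ubiquitin). After quantile normalization its lower correlation with its own group was 0.958 (0.959 before), where other pairs of the same group reached at least 0.988. A different distribution of values on this array therefore does not account for its low correlations. A plain shift or scaling of the array's log2 values leaves a correlation unchanged, so it cannot give these low correlations either. Its part in the array's place on the first principal component was not tested. A lower share of germline transcripts stays open: the germline median was 0.10 higher than on the other GYY4137 arrays (bootstrap interval -0.19 to 0.16), within the range of random lists (-0.24 to 0.14), which by the bound set first would have argued against it, but the oocyte list was at -0.12, with 5 of 23 members higher and only 0.1% of random lists lower. A different stage or composition of that sample stays open too, since moulting and major sperm protein lists were higher on it by 0.56 and 0.40.

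Infection-response genes and genes lowered by active DAF-16 ranked higher after GYY4137. They did not depend on GYY4137 replicate 3 alone, as the lists had camera adjusted p of 1.31e-07 and 8.07e-06 without it, at the preset correlation; with an estimated correlation the adjusted p over all arrays were 0.227 and 0.305. A larger share of intestine cannot be told apart from a change within intestinal cells: the infection-response median exceeded that of 15 intestine markers on no other list by 0.21, with a bootstrap interval from -0.07 to 0.41. An effect of GYY4137, the treatment by which the groups differ, was not tested apart from these and stays open.

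Of the collagen genes, at 1 probe set each, 4 rose and 1 fell, and the pharyngeal genes abu-6 and abu-8 fell. A difference in developmental timing between cultures may account for it and cannot be told apart from an effect of GYY4137: over 118 genes of the collagen, moulting, adult cuticle and pharynx lists, GYY4137 replicate 1 minus control 1 correlated at 0.20 with control 3 minus control 2, below the upper bound of 0.33 from random lists, but with a bootstrap interval over genes from 0.02 to 0.41 that includes it. The bound first set, on the correlation alone, would have argued against timing, and genes are not independent replicates. Over all 9 choices of arrays the correlation ran from 0.00461 to 0.272, with the lowest values, 0.00461, 0.0452 and 0.0824, where GYY4137 arrays were set against control 3. Cross-hybridization between paralogs also stays open, since only 1 of 7 called members, the raised col-183, sat on a probe set with the plain ending, and its control mean of 3.76 lay under the floor.

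The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 121 called probe sets (1 of 10 splits gave as many) and the highest of the others 0. It gave 16 called lists at the preset correlation, and the highest of the others also gave 16 (2 of 10 splits, the real one included); that split set controls 1 and 2 with GYY4137 replicate 2 against the rest.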
